A study of Mus musculus with 15 samples.

How the data were processed

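RNA of newborn (postnatal day 1) mouse pituitaries was pooled by genotype, and each pool was hybridised to 1 Affymetrix Mouse Genome 430 2.0 array, per the labels. RNA was extracted with the Ambion RNAqueous Micro kit and labelled as biotin cRNA. The mice were kept on a high fat laboratory chow, per the labels. The authors processed the arrays with RMA, which corrects background, normalises by quantiles across arrays and summarises probes by median polish. The deposited values are log2 RMA signals. The RMA version and settings are not given in the sources used here. The log2 scale was checked on the values, which lie between 1.83 and 14.8, with the Bacillus control probe sets for TrpnX between 2.31 and 2.84. Medians of the 10 arrays compared ran from 4.31 to 4.43. Arrays give no counts, so their number limits the precision.

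Samples were grouped by title into Pit1 wild type and Pit1 dw/dw, 5 pools each. A further group of 5 arrays shares in the fit below and is not reported here. Pool 1 of Pit1 wild type has a genotype entry at odds with its title, source and strain, and its values were checked against both Pit1 groups. The sex of the pooled pups is not given in the sources used here.

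Of 45101 probe sets, 64 controls were set aside. Of the other 45037, 34945 name 1 gene in the annotation given, 932 name several and 9160 none. The annotation was matched to current gene records by ID for 34741 probe sets, and no symbol changed. Each of 18193 genes was represented by its probe set with the highest mean over all 15 arrays, since 9010 genes have more than 1. Genes whose probe sets have no single name in that annotation were not analysed here.

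The 3 group means were fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with the default prior, a two-sided moderated statistic). P-values were adjusted by Benjamini-Hochberg over all genes in the comparison, with a threshold of 0.05. Counts are also given at a fold of 2 or more. The comparison was Pit1 dw/dw minus Pit1 wild type. Log2 changes are given with the standard error of the fit, group means with the SD over 5 pools. A fall in a count or level is given as a negative log2 change or as a fold lower.

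24 gene lists were fixed before the data were examined, together with 5 genes for the sex of the pools, with 452 members in all, of which 423 were measured. The lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation. Adjustment was over 72 tests, the 24 lists in each of the 3 pairs of groups in the fit. In the 9 list tests of the comparison that passed with the preset correlation, the lists' medians, means and tests have the same sign.

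Genes were named by a rule also fixed then. It takes the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap in any pool, the pituitary hormone genes Gh, Prl, Tshb, Cga, Lhb, Fshb and Pomc whatever their result, and up to 4 members of each list with the smallest adjusted p. Genes named outside it (Socs2, Dio2, Igsf1, and the tissue and sex genes given per pool) were chosen after their values were seen.

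The procedure was tested on simulated data made from the arrays, with 200 of 18193 genes changed in 1 group, 100 by a log2 change of 1 and 100 by a log2 change of 2. It recovered 79% and 99% of them, with 14 false calls among 192 (7.29%), a share above the threshold of 0.05. The simulated noise was normal and independent between genes, with no outlying pools. On the arrays the estimated correlations within lists ran from -0.04 to 0.753. The simulated shares therefore hold for the simulated setting alone.

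Besides leaving out pools, 10 other settings were fixed before the data were examined, each used alone. Values were median centred on each array, normalised by quantiles a second time, or averaged over a gene's probe sets. Probe sets below the overall median of 4.37 on more than 10 arrays were left out, or those ending in _x_at, _s_at or _a_at. Every probe set was also fitted on its own. The fit was given an intensity trend with a robust prior, array weights, only the groups compared, or the replicate number as a block. Each of the 10 pools compared was left out in turn. The 3 alternatives chosen after the data were seen were the ganglion and bone list means as covariates, leaving out pools with a Prph value above 7 (wild-type pool 3 and dw/dw pools 2 and 3 among those compared), and the Xist level as a covariate. Figures were drawn with matplotlib.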

Results

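Pituitary RNA from newborn mice (postnatal day 1) was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per RNA pool. The 10 pools compared fall into 2 groups of 5, Pit1 wild type and Pit1 dw/dw, both on the DW/J background. Pit1 is the POU-domain transcription factor that somatotrophs, lactotrophs and thyrotrophs need, and dw is the Snell dwarf allele. Array medians lay between 4.31 and 4.43 on the log2 scale. The number of arrays limits the precision, and the number of pituitaries in a pool is not given in the sources used here. Pool 1 of Pit1 wild type carries a genotype entry at odds with its title, source and strain. It was placed by 66 genes chosen without it, with 0 for the other wild-type pools and 1 for the dw/dw pools. Its median position was 0.0331, so it was kept in the group its title gives. That scale holds these 2 groups alone, so it does not test for another genotype or strain.

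Pit1 dw/dw against Pit1 wild type asks which genes change in pituitary RNA when Pit1 is mutated, within 1 strain. The RNA was pooled from pituitaries, so a change per cell cannot be told apart from a change in the share of cells. Hormone genes of the Pit1-dependent cells fell: growth hormone (Gh) was at least 42.2-fold lower in dw/dw (8.82 ± 1.33 against 14.22 ± 0.05 log2 units, SD, n = 5 each; adjusted p = 0.00586). Wild-type Gh, at 14.15 to 14.28, lies at the top of the scale of its arrays, so this fold is a lower bound, and the 4 probe sets of Gh fell by 5.40 to 7.77. Thyrotropin beta (Tshb) was 35.1-fold lower (6.77 ± 0.34 against 11.91 ± 0.24; adjusted p = 0.000244), and prolactin (Prl), still low at this age, was at least 2.38-fold lower (3.04 ± 0.13 against 4.29 ± 0.42; adjusted p = 0.00259), a lower bound because the dw/dw values lie near the lower quartile of their arrays (3.05 to 3.22). The receptors through which the hypothalamus drives these cells fell as well, Ghrhr for growth hormone releasing hormone by 4.94 (SE 0.44, adjusted p = 2.89e-05) and Trhr for thyrotropin releasing hormone by 3.17 (SE 0.24, adjusted p = 1.27e-05). The 2 probe sets of Trhr changed by -3.17 and -0.20, and with their mean the change was -1.685. Of the 11 genes in the list of gonadotroph hormones, receptor and regulators, 3 rose and 8 did not pass. Those that rose were the nuclear receptors Nr0b1 (log2 change 1.81, SE 0.25, adjusted p = 0.00187) and Nr5a1 (1.38, SE 0.21, adjusted p = 0.00383) and the gonadotropin releasing hormone receptor Gnrhr (1.49, SE 0.23, adjusted p = 0.00392). The Gnrhr call rests on 1 of its 3 probe sets. The call ended with probe sets ending in _x_at, _s_at or _a_at left out (0.71, adjusted p = 0.26). The Gnrhr probe set used here ends in _a_at.

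Of 18193 genes, 140 passed the threshold in this comparison, 30 higher and 110 lower in dw/dw, and 12 of the higher and 70 of the lower ones changed at least 2-fold. The 2 groups did not overlap in any pool for 505 genes (2.78%), against 0.794% by chance. Among the 10 largest falls were also the protease Pappa2, which cleaves IGF-binding proteins (log2 change -3.70, SE 0.41), the transcription factor Neurod4 (-2.87, SE 0.49), the unconventional myosin Myo15 (-2.60, SE 0.22), the retinoid receptor Rxrg (-2.27, SE 0.29), the glycine receptor subunit Glra2 (-2.25, SE 0.39) and Gnmt, a glycine methyltransferase (-1.99, SE 0.29). Beside the gonadotroph genes, the largest rises were those of the ribonuclease Rnase1 (1.61), the peptide ligand Apela (1.56), Fetub (1.48), Frmpd2 (1.41), Fads2b (1.35), 4930426D05Rik (1.17) and the calcium-binding protein Scgn (1.16). The call of 4930426D05Rik (adjusted p = 0.0276) ended without dw/dw pool 1 (0.0764), 2 (0.0875), 3 (0.0674), 4 (0.0602) or 5 (0.0608) and without wild-type pool 1 (0.0823), 2 (0.0708), 3 (0.0672) or 4 (0.0641), with a range over the alternatives of 0.000561 to 0.0875. With the mean of a gene's probe sets the change was smaller by more than 1.5 times for Apela (0.78), whose other probe set changed by -0.01, and for Neurod4 (-1.83), Nr5a1 (0.80) and Gnrhr (0.75). The dw/dw means of Trhr (3.77), Rxrg (3.78), Glra2 (3.86) and, narrowly, Myo15 (4.366) lie below the median of all values (4.37). So do the wild-type means of Nr0b1 (3.91), Rnase1 (3.73) and Fetub (3.60), and these signals are dim. The count moved by more than 1.5 times when 1 pool was left out: it was 86 without Pit1 wild-type pool 2, 86 without wild-type pool 4, 83 without dw/dw pool 2, 93 without dw/dw pool 4 and 90 without dw/dw pool 5.

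In the list of 12 measured genes of the Pit1 lineage, 8 fell, none rose and 4 did not pass, and 9 fell when adjusted over the list alone. The median change was -1.76, the adjusted p of the list was 1.6e-19, and it was 0.00448 with an estimated correlation. Of the 9 list calls in this comparison, no other passed with an estimated correlation, and without wild-type pool 2 the list calls numbered 5. The gonadotroph list of 11 genes was higher by a median of 0.42 (adjusted p = 7.35e-05, but 0.0985 with an estimated correlation). In it 3 genes rose and none fell, and 5 rose and 1 fell adjusted over the list alone. The gonadotropin subunit genes themselves did not pass, with Lhb at -0.08 (SE 0.77, adjusted p = 0.995), Fshb at -0.70 (SE 0.62, adjusted p = 0.868) and the shared alpha subunit Cga at -0.55 (SE 0.22, adjusted p = 0.482). Lhb and Fshb varied between pools of the same genotype. In wild-type pools 1 to 5 Lhb was 10.19, 9.99, 9.09, 7.71 and 8.35, and Fshb was 7.92, 9.20, 7.17, 6.73 and 6.94. Xist, the RNA of X inactivation, was 11.14, 10.26, 10.19, 3.69 and 10.89. In dw/dw pools 1 to 5 Lhb was 10.25, 7.19, 7.17, 9.98 and 10.36, and Fshb was 8.65, 5.32, 5.11, 7.73 and 7.68. Xist there was 11.03, 4.20, 3.89, 9.82 and 9.60. For Gnrhr, whose other probe sets changed less, the change was 0.71 with probe sets ending in _x_at, _s_at or _a_at left out. The adjusted p of Gnrhr was then 0.26, with a range over the alternatives of 0.000128 to 0.26.

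The corticotroph list was higher by a median of 0.37 over 6 genes (adjusted p = 0.000282, but 0.0985 with an estimated correlation), with no member past the threshold and 2 higher adjusted over the list alone. Its hormone gene Pomc was 14.12 ± 0.06 in dw/dw and 13.93 ± 0.11 in wild type (adjusted p = 0.684), and its regulator Tbx19 changed by 0.68 (SE 0.16, adjusted p = 0.0842). Pomc lies at the top of the scale in dw/dw, where the highest values of the arrays were 14.03 to 14.17. A rise of Pomc could thus be understated. Genes of S phase and mitosis were lower as a list, by a median of -0.29 over 33 genes (adjusted p = 1.35e-07, but 0.330 with an estimated correlation), with no single member past the threshold or adjusted over the list alone. In the melanotroph list, of the intermediate lobe, no gene of 4 passed, and the list did not (adjusted p = 0.995). Its gene Pax7, a transcription factor of melanotrophs, was 8.23 in dw/dw and 8.25 in wild type (adjusted p = 0.991). With dw/dw pools 2 and 3 and wild-type pool 3 went the sensory neuron gene Prph, at 7.79, 9.89 and 10.59 against 3.78 or less in the other 7 pools.

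**Figure D1:**
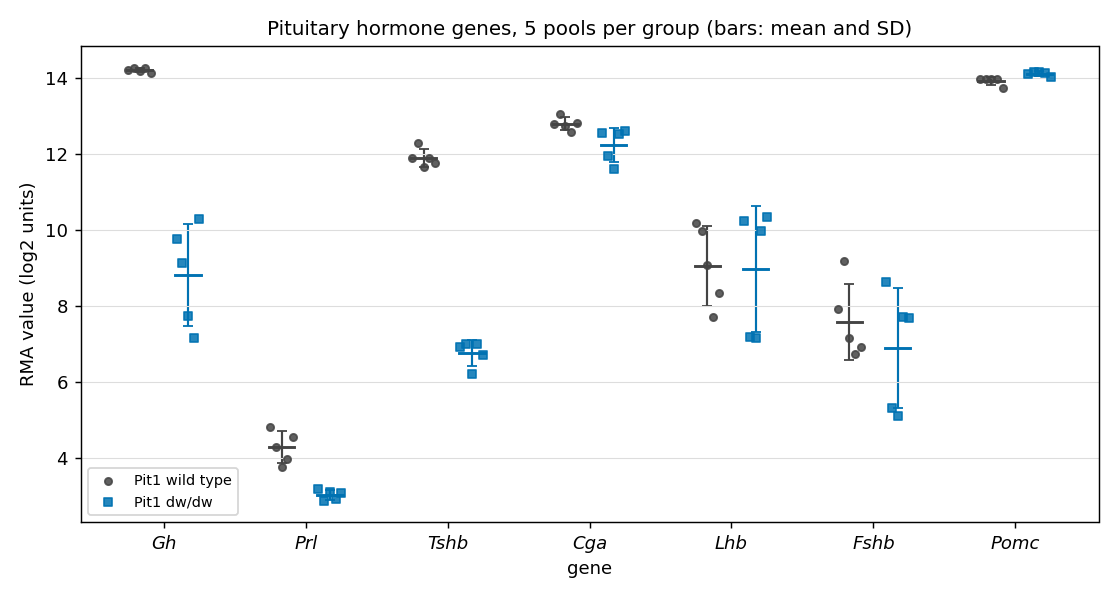
Expression (RMA, log2 units) of 7 pituitary hormone genes in each of 5 pools of Pit1 wild type and Pit1 dw/dw, with bars for the mean and SD. Gh lies near 14.22 in wild type and at a mean of 8.82 in dw/dw.

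Further lists past the threshold in Pit1 dw/dw held no gene past it, also adjusted over the list alone. They were the matrix list (median 0.22, adjusted p = 3.42e-05, but 0.524 with an estimated correlation), the endothelium (0.17, adjusted p = 0.0198, but 0.707), skeletal muscle (0.13, adjusted p = 0.0235, but 0.524), the progenitor list (0.14, adjusted p = 0.0256, but 0.321) and the epithelial and mesenchymal list (0.10, adjusted p = 0.0294, but 0.315). Without wild-type pool 2 the adjusted p was 0.205 for matrix, 0.352 for endothelium, 0.0682 for muscle and 0.1 for the epithelial and mesenchymal list. Without wild-type pool 3 it was 0.0709 for muscle and 0.0654 for the progenitor list, and without wild-type pool 5 it was 0.111 for endothelium and 0.0553 for both muscle and the epithelial and mesenchymal list. Without dw/dw pool 1 it was 0.117 for muscle and 0.0905 for the epithelial and mesenchymal list, without dw/dw pool 4 it was 0.164 for endothelium and 0.115 for the epithelial and mesenchymal list, and without dw/dw pool 5 it was 0.08 for the progenitor list. With array weights all 5 lists lost their call. The adjusted p was then 0.117 for matrix (median 0.03), 0.506 for endothelium, whose median turned to -0.06, and 0.346 for muscle. It was 0.0859 for the progenitor list and 0.117 for the epithelial and mesenchymal list. With probe sets ending in _x_at, _s_at or _a_at left out it was 0.0645 for endothelium and 0.259 for muscle. Without the pools with Prph above 7 it was 0.0632 for muscle. Over all alternatives it ranged from 5.02e-07 to 0.205 for matrix, 0.00129 to 0.506 for endothelium and 0.0033 to 0.346 for muscle. It ranged from 0.00937 to 0.0859 for the progenitor list and 0.00712 to 0.117 for the epithelial and mesenchymal list. Wild-type pool 2 had the lowest mean of the matrix list in its group, -0.80 from the mean of the 10 pools.

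**Figure D2:**
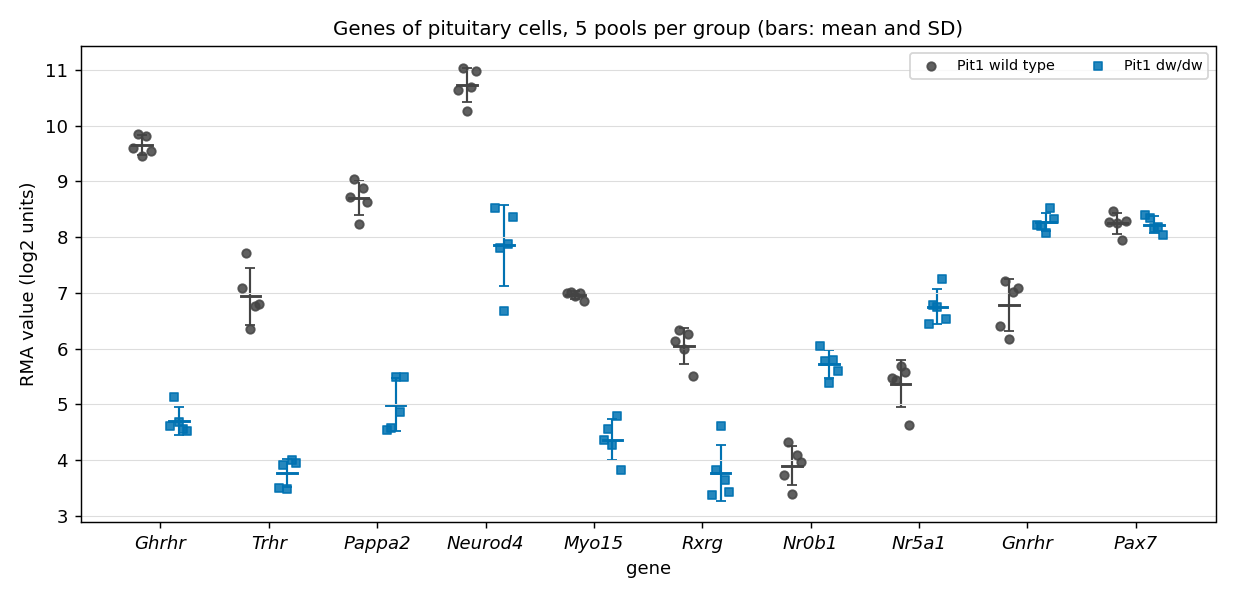
Expression (RMA, log2 units) of 10 genes of pituitary cells in each pool of the 2 groups, with bars for the mean and SD (n = 5). Ghrhr, Trhr and Pappa2 lie lower in all 5 dw/dw pools than in any wild-type pool, Nr0b1 lies higher, and Pax7 lies at 8.23 in dw/dw and 8.25 in wild type.

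The lists of developmental signals did not pass. In the list of BMP, FGF and hedgehog genes (adjusted p = 0.532) Id2, an inhibitor of bHLH factors, rose by 0.86 (SE 0.10, adjusted p = 0.000437), and 1 of 30 genes, the BMP antagonist Chrd, fell (-0.60, SE 0.13, adjusted p = 0.0463). Adjusted over the list alone, 1 rose and 3 fell. With probe sets ending in _x_at, _s_at or _a_at left out, the Id2 change was 0.05 (adjusted p = 0.98, range over the alternatives 0.000113 to 0.98). The 3 probe sets of Id2 changed by 0.05 to 0.93, and the one used here ends in _a_at. The Chrd call ended without dw/dw pool 1 (adjusted p = 0.105), 2 (0.151), 3 (0.0536), 4 (0.102) or 5 (0.117) and without wild-type pool 1 (0.124), 2 (0.128), 3 (0.0957) or 4 (0.129). In all it ended in 19 of 22 alternatives, the replicate number as a block (0.102) among them, and the range over the alternatives was 0.000624 to 0.294. Chrd is dim, with means of 4.31 in wild type and 3.71 in dw/dw, below the median of all values (4.37). In the retinoic acid list (adjusted p = 0.830) Rxrg was the gene of 17 that fell, also adjusted over the list alone, and the list's median (0.07) and test were positive and its mean (-0.05) negative. No gene of the Notch list (23 genes, adjusted p = 0.137) or the Wnt list (44 genes, adjusted p = 0.103) passed, also adjusted over the list alone.

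Among 22 genes of regulated secretion the granin Chgb fell (-0.85, SE 0.18, adjusted p = 0.0396), also adjusted over the list alone, and the other 21 did not pass. The list did not pass (adjusted p = 0.942), its median (-0.01) was negative, and its mean (0.01) and test were positive. The Chgb call ended without dw/dw pool 1 (adjusted p = 0.0537), 2 (0.101), 3 (0.111), 4 (0.0987) or 5 (0.103) and without wild-type pool 1 (0.0941), 2 (0.113) or 4 (0.114), in all in 13 of 23 alternatives, and the range over the alternatives was 0.00218 to 0.196. Among 18 immune genes (adjusted p of the list = 0.159) the antigen presentation gene H2-Aa rose (0.66, SE 0.14, adjusted p = 0.0339), also adjusted over the list alone. The H2-Aa call ended without dw/dw pool 2 (adjusted p = 0.108), 3 (0.104), 4 (0.0874) or 5 (0.0927) and without wild-type pool 1 (0.103), 3 (0.0599), 4 (0.0687) or 5 (0.0689), in all in 17 of 21 alternatives. With the mean of a gene's probe sets the H2-Aa change was 0.16 (adjusted p = 0.709, range over the alternatives 0.00154 to 0.709). The wild-type mean of H2-Aa, 4.13, lies below the median of all values (4.37).

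**Figure D3:**
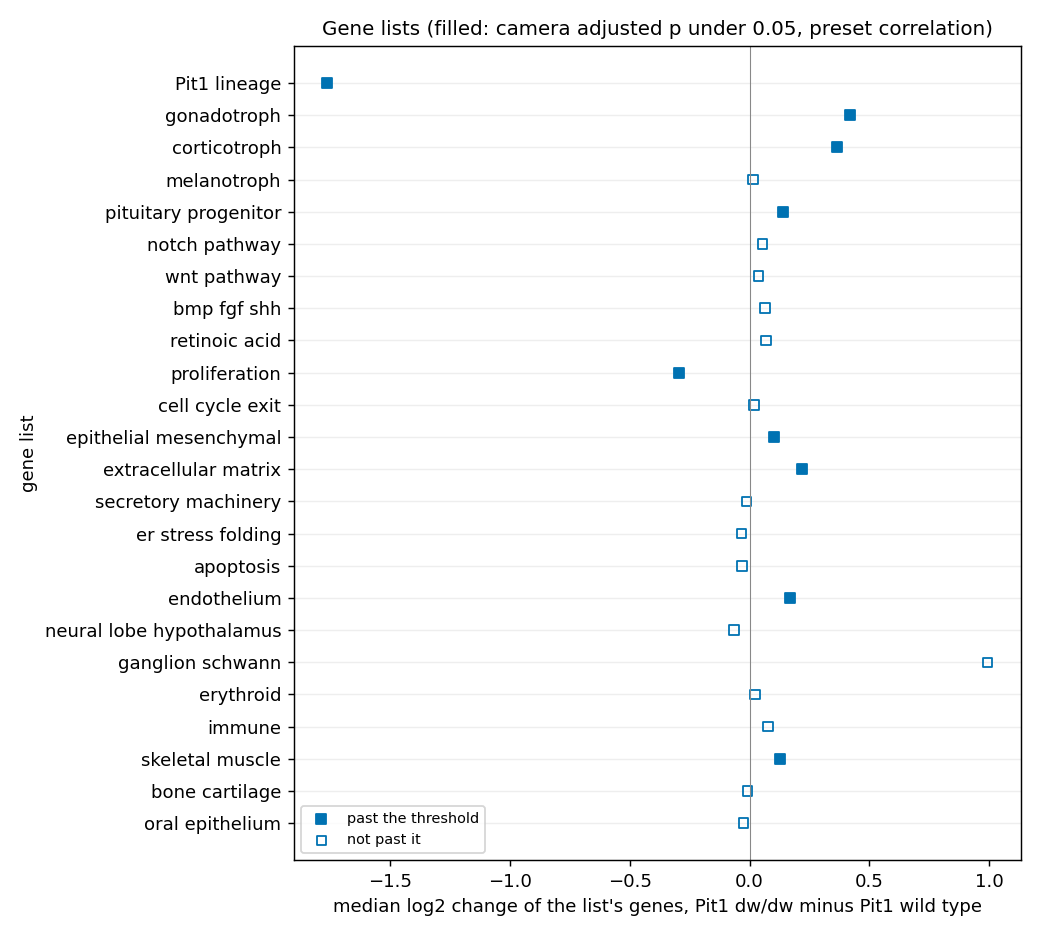
Median log2 change of the measured genes of each of 24 lists in Pit1 dw/dw against Pit1 wild type, filled where the adjusted p with a preset correlation passed. The Pit1 lineage lies at -1.76, the gonadotroph list at 0.42 and the corticotroph list at 0.37.

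No gene passed in the other lists, and none of these lists did: cell cycle exit (adjusted p = 0.985, median 0.02, mean -0.01 and test lower), chaperones and the unfolded protein response (0.608), apoptosis (0.695), neural lobe and hypothalamus (0.346), red cells (0.694), bone and cartilage (0.214, median -0.01, mean 0.02 and test higher) and oral epithelium (0.163, median -0.03, mean 0.15 and test higher). Adjusted over the list alone, 1 gene of neural lobe and hypothalamus was lower and 2 of oral epithelium were higher. The 4 probe sets of Rbl1, of the cell cycle exit list, changed by -0.94 to 0.03. Fitted as single probe sets, 1 of them passed as a fall, while the one used here changed by -0.35 (adjusted p = 0.608). The ganglion and Schwann cell list did not pass either, with a median change of 0.99 (adjusted p = 0.0699). Its genes differed between pools within both groups: Nefl, a neurofilament, was 11.9 in wild-type pool 3 and 11.4 and 10.8 in dw/dw pools 3 and 5, against 6.53 to 9.61 in the other 7. The bone gene Ibsp was 3.03 and 3.13 in wild-type pools 2 and 3 and 8.75 or more in the other 3 wild-type pools. Every count above includes these pools, and leaving out the pools with Prph above 7, a choice made after the data were seen, gave 51 genes from fewer pools. That cut kept dw/dw pool 5, whose ganglion list mean was 0.787 from the mean of the 10 pools. It left out dw/dw pool 2, at 0.775, so the fit is not free of pools high in ganglion genes. With all pools and the ganglion and bone list means as covariates, also chosen after the data were seen, the count was 182. Without the Prph pools the change of Nr5a1 was 1.46 (adjusted p = 0.0594, range over the alternatives 0.000241 to 0.0594). Glra2 at -2.29 (adjusted p = 0.0777, range 0.000598 to 0.0777), Apela at 1.34 (0.117, range 0.000475 to 0.117), Fetub at 1.30 (0.0594, range 0.000128 to 0.0594) and Scgn at 1.17 (0.179, range 0.000669 to 0.179) did not pass without those pools either. With fewer pools these calls ended while the changes stayed close to those with all pools, -2.25, 1.56, 1.48 and 1.16.

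**Figure D4:**
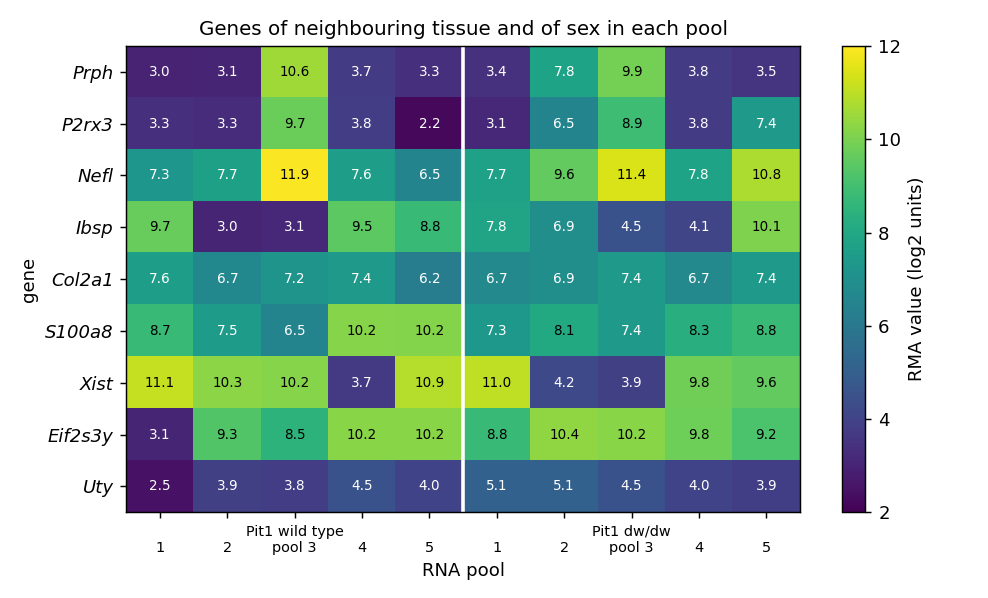
Expression (RMA, log2 units, colour and number) of genes of sensory ganglia, bone and cartilage, neutrophils and sex in each of the 10 pools. Prph is 7.79 or more in 3 pools and Xist is 4.20 or less in 3, dw/dw pools 2 and 3 being among both.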

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

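The search for pools far from the rest of their group was planned. Some of the genes searched, the tissue and sex genes given per pool among them, were chosen after their values were seen. That search marks about 1 in 20 groups by chance, and here it marked 11 of 126 (8.73%). Because of the genes so chosen, this share cannot be set against chance.

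Among genes of the pituitary, these pools stood far from the rest of their group. Ghrhr was 5.13 in dw/dw pool 2, and the next value was 4.69. Nr5a1 was 4.63 in wild-type pool 5 against 5.44 or more in the others. Pomc was 13.74 in wild-type pool 5 against 13.97 or more. Chrd was 3.86 in wild-type pool 5 against 4.36 or more.

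Genes of other tissues and of sex had such pools too. Prph was 10.59 and Nefl 11.94 in wild-type pool 3, where the next values were 3.74 and 7.68. Xist was 3.69 in wild-type pool 4 against 10.19 or more. Eif2s3y, a Y-linked gene, was 3.05 in wild-type pool 1 against 8.45 or more. As list means relative to the 10 pools, the ganglion list was 3.01 in wild-type pool 3 (next -1.03), bone and cartilage 0.96 in dw/dw pool 5 (next -0.02), and cell cycle exit -0.19 in wild-type pool 5 (next 0.05).

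Probe sets without a single gene name, which the comparison does not use, also differed between the groups. Of 10092, 13 passed in Pit1 dw/dw against wild type, 3 higher and 10 lower.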

How the results depend on the processing

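The other settings were fixed before the data were examined; the fits with ganglion and bone covariates, without pools with Prph above 7, and with the Xist level were chosen after the results were seen. The named genes past the threshold gave 28 results, and all kept their direction in each alternative that measured them. For genes chosen because their groups did not overlap in any pool, leaving out a pool could not turn the direction. Filters left some out: 25 were measured with dim probe sets left out, and all 25 kept their call, and 24 with probe sets ending in _x_at, _s_at or _a_at left out, of which 21 kept it and Gnrhr, Id2 and Chrd did not. Of the 28, 25 kept their call with median centring, 26 with a second quantile normalization, 27 with the mean of a gene's probe sets, 25 with every probe set on its own, 26 with an intensity trend, 28 with array weights, 26 with only the groups compared, 27 with the replicate block (all but Chrd, adjusted p = 0.102), 25 with the ganglion and bone covariates, 18 without the Prph pools and 24 with the Xist level. Leaving out 1 pool kept 246 of 280 calls, and 76 of 90 calls of lists. With array weights 571 genes and 5 lists passed; the cause was not tested. Without the Prph pools, with fewer pools per group, 51 genes passed, and with the ganglion and bone covariates 182 did. Leaving out 1 pool gave 83 (without dw/dw pool 2) to 161 genes (without wild-type pool 5). It gave 5 (without wild-type pool 2) to 12 lists (without wild-type pool 1). Wild-type pool 5 had the lowest correlation with the other pools of its group, 0.976. The first principal component of the 10 pools held 35.7% of the variance and did not separate the groups. On it wild-type pools ran from -59.6 (pool 5) to 40.6 and dw/dw pools from -17.9 to 25.2. On the second component, with 15.4% of the variance, the groups did not overlap. Wild-type pools ran there from -6.98 (pool 5) to 31.2 and dw/dw pools from -18.2 to -7.95 (pool 4). With the replicate number as a block 137 genes passed, against 140, and 121 were shared. Pools with the same number were alike in part: 3 of 5 such pairs correlated above 0.1 after group means were removed (range -0.196 to 0.639). The highest was the pair of pool 3. The median was 0.206 for pairs with the same number and -0.0507 for the other pairs across the groups. Among the 5 arrays of the other group, the one with their own number was the best match for 5 of 10 arrays. What this likeness comes from was not tested. Signal limits the dim genes: Prl lies below the median of all values, 4.37, in the wild-type mean and near the lower quartile of the arrays in dw/dw, so its fold is a lower bound.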

Other observations

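The count of genes under other splits of the pools was planned; the count of lists under those splits, Dio2, Igsf1 and Socs2 were chosen after the values were seen. Genes lower in Pit1 dw/dw reached beyond the hormones and their receptors: Dio2, the deiodinase that activates thyroid hormone, changed by -1.68 (adjusted p = 0.00284), the membrane protein gene Igsf1 by -1.69 (adjusted p = 0.0012) and Socs2, an inhibitor of cytokine and growth hormone signalling, by -1.38 (adjusted p = 0.000244), which was -0.91 with the mean of its probe sets. Dio2 was at -1.73 (adjusted p = 0.0594, range over its alternatives 0.000128 to 0.0594) without the pools with Prph above 7.

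The pools differed in genes of sex, which the labels do not describe. Eif2s3y was 3.05 in wild-type pool 1, with Kdm5d, also Y-linked, at 2.27 there. In wild-type pool 4 and dw/dw pools 2 and 3, where Xist was 3.69, 4.20 and 3.89, Eif2s3y was 10.24, 10.35 and 10.22. With the Xist level in the fit, Lhb was at 0.47 (SE 0.59, adjusted p = 0.952) in place of -0.08 (SE 0.77, adjusted p = 0.995), and Fshb at -0.21 (SE 0.43, adjusted p = 0.981) in place of -0.70 (SE 0.62, adjusted p = 0.868).

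Other splits of the same pools tested whether chance gives as many calls. Of 100 splits of the 10 pools, the real one included, 1 gave as many as the 140 genes of Pit1 dw/dw against wild type (highest other 2), so chance is excluded for that count at a share of 0.05. For the 9 lists past the threshold 11 of the 100 splits gave as many, and the highest other gave 11, so chance is not excluded for the number of lists.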
